A study of Homo sapiens with 12 samples.

How the data were processed

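The series holds 12 RNA-seq libraries of polyadenylated RNA from HEK293 cells, an established human embryonic kidney line. Per the labels, confluent cells were held at 39 °C for 12 h, given 50 µM TG003 or its solvent DMSO, and left at 39 °C for another 30 min. The cells then spent 6 h at either 35 °C or 39 °C. The treatment and temperature labels put 3 libraries in each of 4 groups, written here as DMSO_35, DMSO_39, TG003_35 and TG003_39. The labels number the replicates but do not say whether they are separate cultures, so the p-values measure the spread between these samples, which may be technical.

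The authors deposited 1 table per library with 58395 Ensembl gene identifiers, and each table holds TPM, an abundance corrected for transcript length, and estimated read counts per gene. Per the file headers the columns are TPM and read counts. The deposited TPM values are rounded to 1 decimal and sum to between 1001317 and 1001418 in each library, as found from the values. The deposited counts are expected counts, since 23.1% to 24.2% of the genes in each library had values that are not whole, so that a read matching several genes was shared between them. The submitters' processing notes name the genome build hg38. The aligner, the quantification tool, its annotation and the strandedness of the libraries are not given in the sources used here, so counts of antisense, overlapping and near-identical genes are less certain than those of other genes. The extraction label names a DNase digestion and Illumina library preparation.

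Gene symbols, gene types and hg38 coordinates (counted from 1) were taken from GENCODE release 29, which matched 58275 of the identifiers and left 120 without a symbol. Expected counts were rounded to whole numbers, which changed 45.6% of the values above 0. Genes with a mean TPM of at least 1 over the 12 libraries were tested, 20208 in all, and they held at least 99.6% of the counts of every library. Library totals ran from 25.1 to 37.1 M counts. The biological coefficient of variation over all genes was 5.4%.

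The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling factors (0.967 to 1.025), quasi-likelihood fits over all 12 libraries with 1 mean per group, and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. Choices made before the data were examined were the groups, the comparisons, the gene lists, the rule for named genes and most alternatives. The test planned then was limma on log2(TPM + 1). It was replaced by edgeR when the tables turned out to hold counts beside TPM, and the limma fit (limma 3.58.1) is kept as an alternative. Both are tests of change in either direction.

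The comparisons were the temperature effect (35 °C minus 39 °C) in DMSO and in TG003, the TG003 effect (TG003 minus DMSO) at 35 °C and at 39 °C, and the interaction. The interaction is the temperature effect in DMSO minus that in TG003, which equals the TG003 effect at 39 °C minus that at 35 °C. The share of the temperature effect kept under TG003 was measured on genes called in 2 against 2 DMSO libraries. Their median change, signed by the direction of the call, was then taken in the left-out DMSO pair and in all TG003 libraries, in 9 ways. Correlations of log2 changes were computed across genes, with Pearson and Spearman coefficients. Genes are not independent replicates, and 20 simulations of unchanged groups gave the value expected from shared libraries and noise alone.

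There were 29 gene lists with 598 entries, of which 580 matched a gene and 537 were tested. They cover cold-inducible RNA-binding proteins, heat shock, ER chaperones, the ATF4 integrated stress response, CLK and related kinases, SR proteins, hnRNPs, the core spliceosome, transcripts sensitive to nonsense-mediated decay (with stress genes), decay factors, cholesterol synthesis, p53 targets, G2/M, G1/S, homologous recombination, immediate early genes, the circadian clock, AhR targets, NRF2 targets, hypoxia, Wnt targets, interferon response, metallothioneins, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and markers of fibroblasts, leukocytes and epithelium. Each list was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Members past the threshold were counted over all tested genes and adjusted over the list alone.

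Named genes followed 3 rules. In each comparison the 8 largest rises and the 8 largest falls were taken among called genes with a symbol, a mean TPM of at least 5 and no overlap between the 3 values of one group and the 3 of the other (for the interaction, the adjusted p and the TPM only). Names made only of a clone number with a version were not taken as symbols, although 1 of that style, Z97180.1, passed. Up to 4 members with the smallest adjusted p were taken from each list that the text describes. CIRBP, RBM3, CLK1, CLK2, CLK3, CLK4, HSPA1A, HSPH1 and SRSF5 were followed in every comparison. Ratios of genes with 0 counts in a group were set against a floor of 3 counts over that group, and ratios with 1 to 3 counts are given with their exact 95% interval (Clopper-Pearson). A ratio against the floor takes the count of the other group as observed. Its counting error is left out, so such a ratio is no 95% bound. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only.

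Alternatives fixed beforehand were pseudocounts of 0.1 and 5 TPM, no filter, a mean TPM of at least 5, median ratio scaling, quantile normalization, removal of mitochondrially encoded genes, protein-coding genes only, no abundance trend, library weights, the replicate number as a block, fits of the compared groups only, and leaving out each library in turn. For gene lists, an estimated inter-gene correlation was also run, and fry, which tests each list against no change and not against other genes. Ranges of the adjusted p of a list leave fry out. Alternatives chosen after seeing the data were DESeq2 1.42.0, library totals without further scaling, a length offset, the single-library and library-total runs of the list tests, and some alternatives of the correlations. For the mean temperature effect against the mean TG003 effect, and for the TG003 effects at 35 °C and 39 °C, pseudocounts, a mean TPM of at least 5, median ratio scaling, quantile normalization and left-out libraries were fixed beforehand. All other alternatives of the 5 correlations were added. The length offset is the count divided by TPM of each gene and library, which is proportional to the mean length of the transcripts assigned to that gene. It takes out changes in count that come from a change in that length.

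The procedure was tested on simulated counts with 4 sets of 50 changed genes. Of the genes changed by 0.25, 0.5, 1 and 2 on the log2 scale between temperatures in DMSO, edgeR called 34%, 74%, 98% and 98%, and between 0 and 14 of 20008 unchanged genes in each comparison. Of interactions of 0.125, 0.25, 0.5 and 1 it called 0%, 12%, 46% and 84%, so that a small interaction was often missed. Only these 4 sets of 50 among 20208 genes were changed, with as many rises as falls. In the data, 29.9% to 61.9% of the tested genes were called in each comparison. The simulation thus does not test the scaling where many genes change, and its rates need not carry over to the data. A simulated share kept of 0.5 was estimated as 0.52 ± 0.02 (SD over the 9 ways). No library was left out, and no pair of replicates agreed within sampling noise, with chi-square values per degree of freedom between 2.318 and 13.134.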

Results

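Polyadenylated RNA was sequenced from 12 samples of HEK293 cells, 3 in each of 4 groups. Cells had been kept at 39 °C and then spent 6 h at 35 °C or 39 °C, with the solvent DMSO or with TG003, an inhibitor of the CLK protein kinases that phosphorylate splicing factors. Library totals were 25.7 ± 0.9 M counts in DMSO_35, 34.4 ± 3.2 in DMSO_39, 29.6 ± 2.1 in TG003_35 and 28.1 ± 3.0 in TG003_39 (SD, n = 3 each). Per library, between 25.1 and 37.1 M counts were assigned to genes. Log expression of replicates of a group correlated across genes at r between 0.9932 and 0.9956, where genes are not independent replicates. In a principal component analysis the first component held 57.6% of the variance, with the DMSO libraries between -52.63 and -33.8 and the TG003 libraries between 15.18 and 71.29. Mitochondrially encoded genes took 9.53% ± 0.16 of the counts in DMSO_35, 8.05% ± 0.23 in DMSO_39, 9.95% ± 0.12 in TG003_35 and 9.41% ± 0.12 in TG003_39 (SD, n = 3 each).

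Unless a fold is given, changes are log2 ratios with their standard error, from edgeR over 3 against 3 libraries. Values in TPM are means ± SD over 3 libraries, and positions are those of hg38. Genes named for the size of their change were chosen among called genes with no overlap between the 3 TPM values of one group and the 3 of the other, a condition not set for the interaction. Other fits moved some of the called changes of named genes by more than 1.5-fold. The counts that follow cover only changes that kept their call and direction, so moves that ended or turned a call are left out. With a pseudocount of 5 TPM, 66 came nearer to 0 and 2 moved away from it. With 1 TPM these numbers were 18 and 9, with 0.1 TPM 2 and 8, and with quantile normalization 17 and 9. Library weights brought 9 nearer to 0 and the length offset 2, and neither moved any away.

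The shift from 39 °C to 35 °C in solvent-treated cells shows how RNA levels follow temperature without the inhibitor. CIRBP and RBM3, which encode RNA-binding proteins known to be induced by mild cold, rose 1.65-fold and 1.63-fold. CIRBP (ENSG00000099622, chromosome 19, 1259384 to 1274880) had 298 ± 18.8 TPM at 35 °C and 186 ± 2.90 at 39 °C. RBM3 (ENSG00000102317, chromosome X, 48574449 to 48579066) had 135 ± 5.76 and 82.0 ± 4.30 TPM, with adjusted p = 8.65e-10 for CIRBP and 3.29e-09 for RBM3. CLK1 (ENSG00000013441, chromosome 2, 200853009 to 200864744), a kinase that phosphorylates SR splicing factors, was 2.2-fold lower at 35 °C, with 43.5 ± 4.44 against 87.2 ± 0.794 TPM (adjusted p = 5.26e-10). HSPA8 (ENSG00000109971, chromosome 11, 123057489 to 123063230), a chaperone of the HSP70 family, was 3.04-fold lower at 35 °C, with 126 ± 5.92 against 375 ± 9.68 TPM (adjusted p = 8.85e-13).

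**Figure D1:**
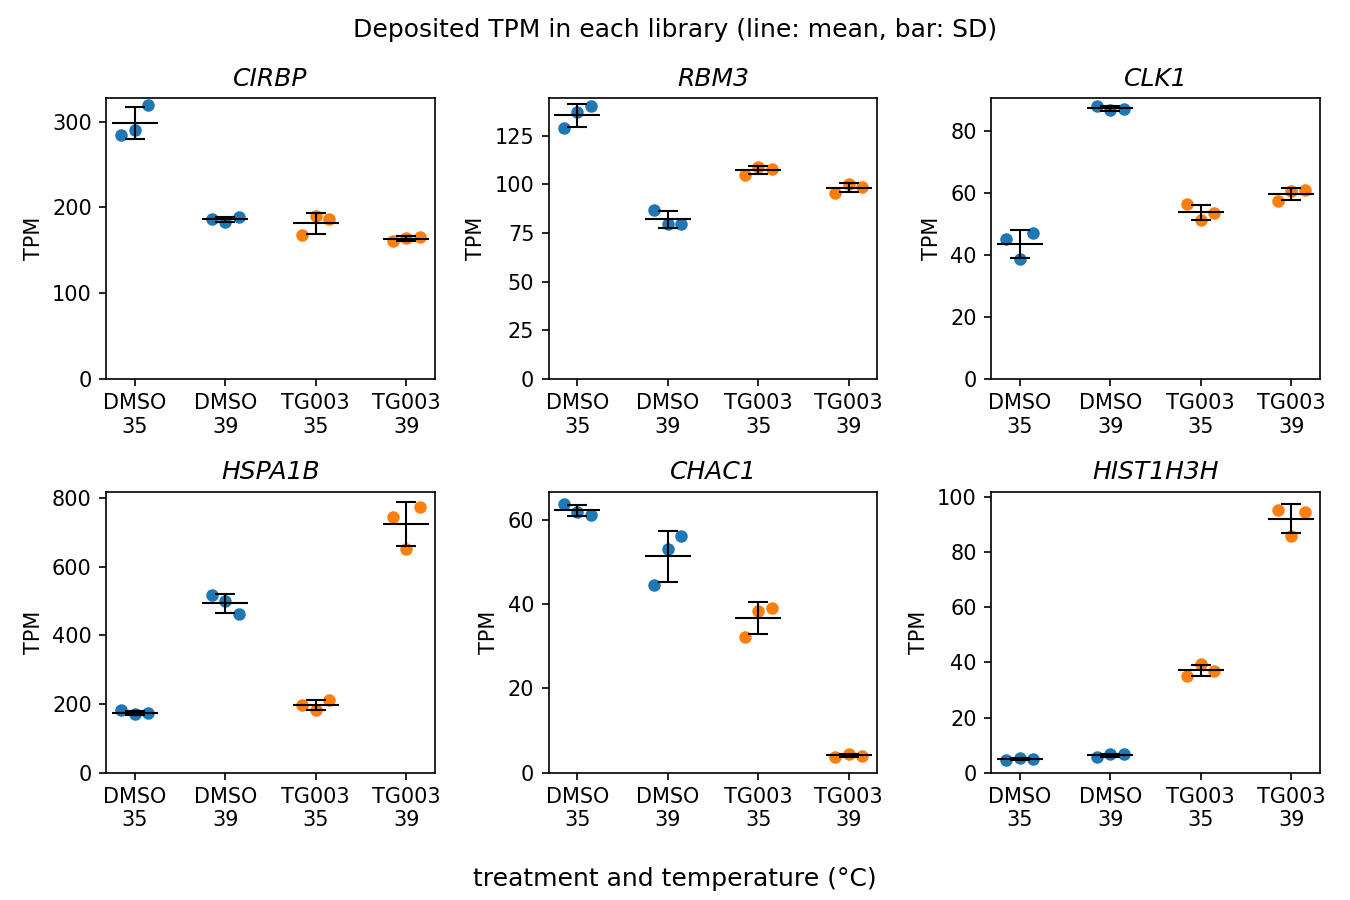
TPM of CIRBP, RBM3, CLK1, HSPA1B, CHAC1 and HIST1H3H in each of the 12 libraries, by group, with 1 panel per gene, 1 point per library, a line at the group mean and bars of 1 SD (n = 3). CIRBP was highest in DMSO_35 with a mean of 298 TPM, and HIST1H3H was highest in TG003_39 with a mean of 92.1 TPM.

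Of 20208 genes tested in this comparison, 4207 rose and 4820 fell, 44.7% in all, and 437 and 358 of them changed at least 2-fold. The share higher was 46.6%, but 52.9% with library totals alone (4787 and 4265) and 51.8% with quantile normalization (3610 and 3364). The 2-fold counts, higher and lower, were 156 and 154 with limma, 98 and 107 from a mean TPM of 5, and 972 and 598 without a filter. Of 32 heat shock genes, 21 fell and 2 rose (median -0.21, adjusted p = 6.03e-06, and 0.353 as adjusted p with an estimated correlation). HSPA1B fell by 1.47 (175 ± 5.81 against 493 ± 27.7 TPM), DNAJB1 by a change of -1.34 and DNAJA1 by a change of -0.98. Heat shock genes adjusted over the list alone gave 22 lower and 2 higher. Of 15 kinases of the CLK family and its relatives, 13 fell and none rose (median -0.33, adjusted p = 6.13e-05, and adjusted p = 0.251 with an estimated correlation), among them PRPF4B (-0.90 ± 0.07), HIPK1 (-0.48 ± 0.04) and HIPK2 (-0.55 ± 0.05). These kinases adjusted over the list alone gave 13 lower and 1 higher. Of 21 genes of cholesterol synthesis and uptake, 14 fell and 1 rose (median -0.34, adjusted p = 6.13e-05, and adjusted p = 0.251 with an estimated correlation). They include SQLE at -1.07 ± 0.07, MSMO1 at -1.37 ± 0.12, INSIG1 at -0.93 ± 0.08 and HMGCR, the enzyme targeted by statins, at -0.75 ± 0.06. Cholesterol genes adjusted over the list alone gave 15 lower and 1 higher. Of 26 genes of G2 phase and mitosis, 11 fell and 1 rose (median -0.15, adjusted p = 0.0175, and adjusted p = 0.556 with an estimated correlation), with CENPE at -0.58, CENPF at -0.52, DLGAP5 at -0.48 and ANLN at -0.47. When adjusted over the list alone, 12 of the mitotic genes fell and 2 rose. Over 20 alternatives the adjusted p ran from 5.14e-05 to 0.251 for the kinases, 3.81e-05 to 0.251 for cholesterol genes and 0.0115 to 0.556 for mitotic genes.

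Of 25 targets of ATF4, the transcription factor of the integrated stress response, 15 rose and 3 fell at 35 °C (median 0.27, adjusted p = 0.000536, and adjusted p = 0.483 with an estimated correlation). The same counts were found adjusted over the list alone. PPP1R15A, a subunit that directs eIF2alpha dephosphorylation, rose 2.4-fold, SLC7A11 1.86-fold, SESN2 1.85-fold and ATF3 1.5-fold. Of 13 mitochondrially encoded genes, 10 rose and none fell (median 0.21, adjusted p = 1.49e-05, and adjusted p = 0.52 with an estimated correlation), while quantile normalization put their median at 0.00 (adjusted p = 0.66). That scaling gives equal ranks equal values in every library, and these 13 genes held ranks between 1 and 16 in all of them, so it leaves them little room to change. Adjusted over the list alone, 11 rose. MT-ND1 rose by 0.66 ± 0.04 and MT-CO3 by 0.50 ± 0.04, while MT-CO2 (0.40 ± 0.03) and MT-ND2 (0.39 ± 0.04) lost their calls with quantile normalization (adjusted p = 0.34 and 0.0515, lowest over 27 alternatives 2.1e-28 and 4.39e-24). Over 20 alternatives the adjusted p of the mitochondrial list ran from 3.92e-06 to 0.66, that of the heat shock list from 2.23e-06 to 0.353 and that of the ATF4 list from 0.000267 to 0.483.

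A pair of lists was called near the threshold in this comparison. Of 20 genes of ER chaperones and the unfolded protein response, 7 rose and 2 fell (median 0.06, adjusted p = 0.0416, and adjusted p = 0.556 with an estimated correlation), with XBP1 at 0.67 ± 0.04, HERPUD1 at 0.53 ± 0.04 and HSPA5 at 0.42 ± 0.04. EDEM1 rose 1.17-fold, a call lost with limma (adjusted p = 0.124) and with the length offset (0.08), over a range of 2.33e-07 to 0.135. Of 18 transcripts sensitive to nonsense-mediated decay or to stress, 7 rose and 5 fell (median 0.07, adjusted p = 0.0416, and adjusted p = 0.556 with an estimated correlation), with GADD45A at 1.03, SNHG17 at 0.85, SNHG15 at 0.74 and SNHG1 at 0.46. For both lists the counts adjusted over the list alone were equal to those over all genes. With the replicate number as a block the ER list lost its call (0.0817). So it did with the length offset (0.0578), limma (0.116) and quantile normalization (0.0805), over a range of 0.0218 to 0.556. It also lost it without DMSO_35 replicate 1 (0.0534), TG003_35 replicate 1 (0.0583), replicate 2 (0.0559) or replicate 3 (0.0515), or DMSO_39 replicate 2 (0.0821). With the same block the decay list lost its call (0.0986). So it did with the length offset (0.0578), limma (0.116) and quantile normalization (0.166), over a range of 0.0243 to 0.556. Without DMSO_35 replicate 1, without any 1 library of TG003_35, DMSO_39 or TG003_39, its adjusted p lay between 0.0506 and 0.143.

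The largest rises at 35 °C in DMSO were those of ST7-AS1 (6.09-fold, 10.8 ± 0.651 against 1.8 ± 0.3 TPM, adjusted p = 1.74e-11) and ZNF587B (5.92-fold, 29.4 ± 1.82 against 5.03 ± 0.493 TPM, adjusted p = 7.53e-12). ST7-AS1 is an antisense gene and PABPC1P3 (4.17-fold), SLC16A6P1 (4.03-fold), FAM86HP (3.6-fold) and FAM86C2P (3.16-fold) are pseudogenes, whose counts depend on how reads were assigned. MATN1-AS1 rose 3.17-fold and LIPT2, an enzyme of lipoate attachment, 3.02-fold. The largest falls were those of the pseudogene RPS3AP38 (-2.80 ± 0.24), IFI27 (-2.07 ± 0.15), SOS1-IT1 (-1.78 ± 0.21), PANK1, a kinase of coenzyme A synthesis (-1.77 ± 0.07), and MRPL23-AS1 (-1.68 ± 0.10). The small RNA RNU12-2P had 1 count in DMSO_35 and 11 in DMSO_39, an 8.21-fold ratio (95% interval 1.19 to 353). Its call (adjusted p = 0.0368) was lost without DMSO_35 replicate 1 or 2 or any 1 library of DMSO_39 (0.0555 to 0.121, and 0.00203 to 0.121 over 26 alternatives), and its change was -4.73 without DMSO_35 replicate 3. RF01979, with 6 counts against 28, was at -1.77 ± 0.65 (adjusted p = 0.0335) and lost its call without DMSO_35 replicate 3, DMSO_39 replicate 1 or DMSO_39 replicate 3 (0.0508 to 0.127, and 0.0226 to 0.127 over 27 alternatives).

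Among the other genes followed throughout, HSPH1 (-0.76 ± 0.06), HSPA1A (-0.71 ± 0.17), SRSF5 (-0.51 ± 0.04) and CLK2 (-0.34 ± 0.04) fell at 35 °C in DMSO. The fall of SRSF5, an SR splicing factor, was -0.13 with the length offset (adjusted p = 0.0486). CLK4 fell by 0.33 (adjusted p = 0.00299), a call lost with limma (0.107), the length offset (0.101) and quantile normalization (0.287), over a range of 1.1e-05 to 0.287. CLK3, at -0.12 (adjusted p = 0.0391), lost its call in 20 of 28 alternatives (0.0183 to 0.196). These include leaving out DMSO_35 replicate 2 or 3, TG003_35 replicate 3, DMSO_39 replicate 2 or 3, or any 1 library of TG003_39 (0.0564 to 0.16).

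Counts of replication-dependent histone genes rose with TG003 at 35 °C. Their messages normally end in a stem-loop without a poly(A) tail, so libraries of polyadenylated RNA do not measure total histone RNA. All 14 tested histone genes rose (median 2.60, adjusted p = 2.35e-17, and adjusted p = 0.00711 with an estimated correlation), and all 14 rose adjusted over the list alone. HIST1H3H (ENSG00000278828, chromosome 6, 27810064 to 27811300) rose 7.77-fold, from 5 ± 0.265 to 37.1 ± 2.06 TPM. HIST2H2BE rose 6.28-fold, HIST1H2AC 5.87-fold and HIST1H1C 3.86-fold. LEFTY1 (ENSG00000243709, chromosome 1, 225886282 to 225911382), a secreted antagonist of Nodal signalling, rose 22.5-fold, from 0.467 ± 0.306 to 10.9 ± 0.208 TPM. PYCARD (ENSG00000103490, chromosome 16, 31201485 to 31203450), an inflammasome adaptor, rose 22.2-fold, from 0.633 ± 0.351 to 13.2 ± 3.08 TPM.

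In this comparison 4788 genes rose and 4800 fell, 47.4% of those tested, and 1115 and 179 of them changed at least 2-fold. The share higher was 49.9%, against 42% with limma (3571 and 4927) and 40.8% with quantile normalization (3426 and 4978). The 2-fold counts, higher and lower, were 581 and 88 with limma, 438 and 154 with quantile normalization, and 1929 and 400 without a filter. Of 25 ATF4 targets, 18 fell and 2 rose (median -0.31, adjusted p = 7.86e-06, and adjusted p = 0.259 with an estimated correlation), with the amino acid transporters SLC7A11 at -1.34 ± 0.09, SLC3A2 at -0.66 ± 0.04 and SLC7A5 at -0.43 ± 0.05, and CEBPB at -0.88 ± 0.09. Adjusted over the list alone, 19 fell and 2 rose. Of 21 cholesterol genes, 12 rose and 1 fell, and the same adjusted over the list alone (median 0.19, adjusted p = 0.00105, and adjusted p = 0.268 with an estimated correlation). HSD17B7 rose 1.91-fold, INSIG1 1.7-fold, LDLR 1.54-fold and HMGCR 1.48-fold. Of 11 Wnt targets, 7 fell and none rose (median -0.35, adjusted p = 0.00105, and adjusted p = 0.0627 with an estimated correlation), with LGR5 at -1.19 ± 0.08, NKD2 at -0.50 ± 0.08, NKD1 at -0.43 ± 0.06 and LEF1 at -0.38 ± 0.06. Adjusted over the list alone, 8 fell. Over 20 alternatives the adjusted p of the Wnt list ran from 0.000707 to 0.0627, that of the ATF4 list from 4.97e-07 to 0.259 and that of the cholesterol list from 0.000265 to 0.268.

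Of 76 ribosomal protein genes, 35 rose and none fell with TG003 at 35 °C (median 0.11, adjusted p = 0.00105, and adjusted p = 0.737 with an estimated correlation), but quantile normalization turned the median to -0.02 (adjusted p = 0.75). The same 35 were counted adjusted over the list alone. The call was also lost with the length offset (median 0.07, adjusted p = 0.0762) and with limma (0.03, adjusted p = 0.26), over a range of 1.13e-05 to 0.75. RPL14 rose 1.36-fold and RPL28 1.19-fold, yet quantile normalization turned them to -0.08 and -0.09, limma to -0.03 and -0.04, and the length offset put both at 0.01. Their adjusted p over 28 alternatives ran from 4.37e-26 to 0.818 and from 1.96e-09 to 0.906. RPS23 rose 1.31-fold and RPL37 1.34-fold, calls lost with limma (adjusted p = 0.0741 and 0.157) and quantile normalization (0.172 and 0.789), with lowest values of 6.16e-22 and 1.09e-19.

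The other large rises at 35 °C were those of HIST1H2BF (14.5-fold), C3orf86 (13.8-fold) and CCDC13 (12.4-fold). The largest falls were those of ZNF587B (-2.16 ± 0.10), the pseudogene SLC16A6P1 (-1.85 ± 0.16), WSB1, part of a ubiquitin ligase (-1.72 ± 0.06, adjusted p = 5.43e-13), and Z97180.1 (-1.44 ± 0.13). They also include GCSHP5 (-1.43 ± 0.23), SNHG4 (-1.41 ± 0.10), AMH (-1.40 ± 0.09) and PDCD4, an inhibitor of translation initiation (-1.42, 56.5 ± 4.54 against 170 ± 1.65 TPM, adjusted p = 2.03e-12). The small RNA SNORA54 had 0 counts in DMSO_35 and 10 in TG003_35, 2.89-fold higher against the floor of 3 counts, which is no lower bound. It lost its call (adjusted p = 0.0226) without any 1 library of DMSO_35 or without TG003_35 replicate 1 (0.0508 to 0.0568, and 0.00209 to 0.081 over 27 alternatives). The pseudogene HIST1H2APS3, with 0 and 7 counts, was 2.02-fold higher against that floor. It lost its call (0.0265) without any 1 library of DMSO_35 or without TG003_35 replicate 2 or 3 (0.0502 to 0.0674, and 8.61e-11 to 0.0941 over the alternatives). RNA5SP67, with 0 and 6 counts, was 1.73-fold higher against the same floor. It lost its call (0.0487) without any 1 library other than TG003_35 replicate 2 (0.0535 to 0.13, and 0.00153 to 0.132 over the alternatives).

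CIRBP fell with TG003 at 35 °C by 0.76 (181 ± 12.1 against 298 ± 18.8 TPM, adjusted p = 2.7e-10) and RBM3 by 0.27 (adjusted p = 0.00015). SRSF5 rose 1.49-fold, CLK2 1.26-fold and CLK1 1.25-fold. The mean length of the transcripts assigned to SRSF5 rose by 0.281 ± 0.044 (log2), which raises its counts relative to its TPM. HSPA1A (-0.12, adjusted p = 0.635) and CLK3 (0.10, adjusted p = 0.079) did not pass. CLK3 passed with a filter of 5 TPM (0.0197), with protein-coding genes alone (0.00922) and with library weights (0.046). HSPH1 rose 1.13-fold (adjusted p = 0.0136), a call lost with limma (0.0571) and without DMSO_35 replicate 2 or TG003_35 replicate 1 (0.0691 and 0.0871), over a range of 0.00264 to 0.0871. CLK4 fell by 0.23 (adjusted p = 0.0315). Its call was lost with a filter of 5 TPM (0.0606), with protein-coding genes alone (0.0843), and without DMSO_35 replicate 3, TG003_35 replicate 2 or TG003_35 replicate 3 (0.0903 to 0.169, lowest over 28 alternatives 0.00251), and its change was -0.15 without DMSO_35 replicate 3.

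TG003 at 39 °C changed more genes than the other comparisons, with 6103 higher and 6410 lower, 61.9% of those tested, and 1746 and 805 of them by at least 2-fold. The histone genes rose again, 14 of 14, and 14 adjusted over the list alone (median 2.86, adjusted p = 1.91e-12, and adjusted p = 0.0437 with an estimated correlation). HIST1H3H rose 16.3-fold, from 6.33 ± 0.551 to 92.1 ± 5.24 TPM, and HIST2H2BE 14.4-fold, from 10.3 ± 0.907 to 133 ± 18.9 TPM. HIST1H2BD rose 9.06-fold and HIST1H2AC 8.31-fold. Of 25 ATF4 targets, 24 fell and none rose, and the same adjusted over the list alone (median -0.84, adjusted p = 3.87e-12, and adjusted p = 0.0457 with an estimated correlation). CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519), an enzyme that degrades glutathione, was 11.6-fold lower, with 4.07 ± 0.379 against 51.3 ± 6.06 TPM (adjusted p = 1.72e-14). SESN2 was at -1.95 ± 0.06, the serine synthesis enzyme PSAT1 at -1.04 ± 0.04 and STC2 at -0.90 ± 0.04. With limma on log2(TPM + 1) 4068 genes were higher and 7489 lower, 35.2% higher against 48.8% with edgeR, and the median of all genes in that fit was -0.107. The 2-fold counts, higher and lower, were 970 and 596 with limma, 942 and 512 with quantile normalization, and 3407 and 1243 without a filter.

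Of 76 ribosomal protein genes, 73 rose and none fell with TG003 at 39 °C, and 73 adjusted over the list alone (median 0.30, adjusted p = 8.34e-14, and adjusted p = 0.484 with an estimated correlation). Quantile normalization put their median at 0.02 (adjusted p = 0.252), over a range of 1.52e-15 to 0.484. RPL14 rose 1.84-fold, RPL27A 1.55-fold, RPL28 1.54-fold and RPS23 1.46-fold, but not with quantile normalization (adjusted p = 0.478, 0.508, 0.603 and 0.47), and RPS23 not with limma (0.0641). With the length offset RPL14 was at 0.27, against 0.88 without it. The lowest adjusted p of these 4 genes over 28 alternatives lay between 2.1e-107 for RPL14 and 2.05e-48 for RPS23. Of 13 mitochondrially encoded genes, 12 rose and none fell (median 0.25, adjusted p = 0.00315, and adjusted p = 0.548 with an estimated correlation), while quantile normalization, which leaves genes of the top ranks little room to change, put the median at 0.00 (adjusted p = 0.843) and turned MT-CO2 to -0.07 (adjusted p = 0.0423). The list was also lost with limma (0.061), over a range of 0.00043 to 0.843, and 13 rose adjusted over the list alone. MT-ND4L rose 1.28-fold, MT-ND4 1.27-fold, MT-ND6 1.25-fold and MT-CO2 1.19-fold, the latter not with limma (adjusted p = 0.0645, range 4.9e-12 to 0.0805).

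Of 11 Wnt targets, 10 fell and none rose at 39 °C (median -0.56, adjusted p = 0.000822, and adjusted p = 0.0457 with an estimated correlation), and 11 fell adjusted over the list alone. LGR5, a receptor of stem cells, was at -1.71 ± 0.09, NKD2 at -0.91 ± 0.08, LEF1 at -0.64 ± 0.06 and NKD1 at -0.53 ± 0.07. NKD1 lost its call with limma (adjusted p = 0.0683), over a range of 1.12e-10 to 0.0739. Of 18 transcripts sensitive to decay or to stress, 15 rose and 3 fell, and the same adjusted over the list alone (median 0.30, adjusted p = 0.00367, and adjusted p = 0.484 with an estimated correlation). SNHG1 was at 0.87 ± 0.04, GADD45B at 0.85 ± 0.07, SNHG15 at 0.72 ± 0.05 and SNHG12 at -0.82 ± 0.06. The list mixes both kinds, so its test does not single out targets of decay. Of 32 heat shock genes, 18 rose and 4 fell, and the same adjusted over the list alone (median 0.15, adjusted p = 0.00466, and adjusted p = 0.539 with an estimated correlation). DNAJA4 rose 3.02-fold, UBC 1.63-fold, DNAJB1 1.59-fold and HSPH1 1.56-fold. The adjusted p of the decay list ran from 0.00237 to 0.484 over 20 alternatives. The heat shock list was lost with quantile normalization (0.115), over a range of 0.00237 to 0.539. Of 21 cholesterol genes, 12 rose and 3 fell, and the same adjusted over the list alone (median 0.31, adjusted p = 0.0116, and adjusted p = 0.484 with an estimated correlation). HSD17B7 rose 1.9-fold, SQLE 1.84-fold, HMGCS1 1.79-fold and NSDHL 1.57-fold, and the list was lost with limma (0.0501, range 0.00454 to 0.484).

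Among splicing factors, 23 of 36 genes of the core spliceosome rose with TG003 at 39 °C and 5 fell, or 24 and 5 adjusted over the list alone (median 0.21, adjusted p = 0.0116, and adjusted p = 0.484 with an estimated correlation). PRPF3 rose 2.12-fold and U2AF1, which binds the end of introns, 1.79-fold, while SNRPA1 (-0.91 ± 0.04) and LUC7L (-0.90 ± 0.06) fell. The call was lost with limma (0.0501) and quantile normalization (0.108), over a range of 0.0071 to 0.484. Of 24 hnRNP genes, 16 rose and 8 fell, and the same adjusted over the list alone (median 0.24, adjusted p = 0.0489, and adjusted p = 0.58 with an estimated correlation). PTBP2 rose 2.15-fold, HNRNPH2 1.78-fold and HNRNPR 1.77-fold, and PTBP3 fell by 1.27. The hnRNP call was lost with limma (median 0.06, adjusted p = 0.052), quantile normalization (0.04, 0.299) and the replicate number as a block, over a range of 0.00736 to 0.58. It was also lost without any 1 library of DMSO_35 or TG003_35, DMSO_39 replicate 2 or 3, or TG003_39 replicate 2 (0.0508 to 0.0839).

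The other large rises at 39 °C were those of PYCARD (56.4-fold), HIST1H2BF (32.3-fold), CMYA5 (ENSG00000164309, 30.8-fold, 18 ± 0.819 against 0.733 ± 0.306 TPM), the pseudogene BTF3P6 (26.6-fold) and EFCAB12 (24.5-fold). OPRD1 (ENSG00000116329, chromosome 1, 28812142 to 28871267), the delta opioid receptor, rose 21.5-fold, from 1.17 ± 0.0577 to 21.1 ± 2.67 TPM. SNORA50A, a small nucleolar RNA with 0 counts in DMSO_39 and 48 in TG003_39, was 19.6-fold higher against the floor of 3 counts (adjusted p = 6.59e-06). The pseudogene HIST1H2APS3 had 0 and 8 counts and was 3.26-fold higher against that floor (adjusted p = 0.00651). The largest falls after CHAC1 were those of SLC25A32, a mitochondrial folate carrier (-2.75 ± 0.11), MIR17HG (-2.62 ± 0.17), INHBE (-2.53 ± 0.11), TRAF5 (-2.50 ± 0.08), CTH, which makes cysteine from cystathionine (-2.27 ± 0.05), ANKRD10-IT1 (-2.21 ± 0.26) and the amino acid transporter SLC38A2 (4.55-fold lower).

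RBM3 rose 1.43-fold with TG003 at 39 °C (98.3 ± 2.39 against 82.0 ± 4.30 TPM, adjusted p = 4.11e-08), while CIRBP fell by 0.19 (164 ± 2.70 against 186 ± 2.90 TPM, adjusted p = 0.00106). The TPM of RBM3 rose less than its counts, and the mean length of its assigned transcripts rose by 0.098 ± 0.014 (log2). The fall of CIRBP was lost with the length offset (-0.06, adjusted p = 0.302, range 3.04e-05 to 0.302). CLK1 fell by 0.57 (59.7 ± 1.97 against 87.2 ± 0.794 TPM, adjusted p = 4.26e-07) and CLK4 by 0.41, while CLK2 rose 1.31-fold. HSPA1A rose 1.6-fold, but not with quantile normalization (adjusted p = 0.0605, range 7.25e-06 to 0.0605). CLK3 rose 1.19-fold, but was at 0.01 with limma (adjusted p = 0.902) and 0.04 with quantile normalization (0.48), against a lowest value of 4.87e-07. SRSF5 rose 1.09-fold (adjusted p = 0.0149). Its call was lost without a filter (0.128), with quantile normalization (0.162) and without DMSO_39 replicate 2 (0.104), over a range of 0.000339 to 0.162.

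Gene classes differed in how their called genes split. With TG003 at 39 °C, 1503 long noncoding genes were higher and 512 lower, and 636 pseudogenes were higher and 223 lower. That is 74.6% and 74% higher, against 40.8% of called protein-coding genes. At 35 °C the shares higher were 78% of long noncoding genes, 81.9% of pseudogenes and 41.2% of protein-coding genes. For temperature in DMSO they were 54.4%, 49.7% and 45.1%. For temperature in TG003 the classes stood the other way, with 42.5%, 40.2% and 51.6% higher. In the interaction 62.9%, 51.7% and 40.5% of the called genes were positive.

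**Figure D2:**
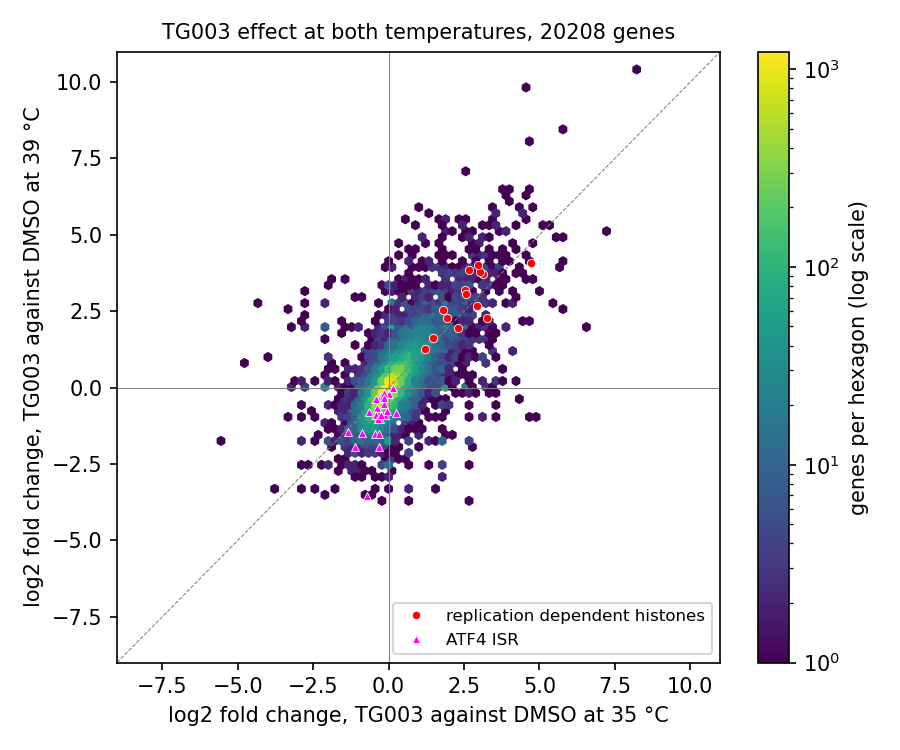
Log2 change with TG003 at 35 °C (horizontal axis) and at 39 °C (vertical axis) of 20208 genes, as a density of genes per hexagon, with 14 histone genes as red circles, 25 ATF4 targets as magenta triangles and equal change as a dashed line. The histone genes lie at 1.22 to 4.73 at 35 °C and 1.25 to 4.08 at 39 °C, and the correlation across genes was 0.669.

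The shift to 35 °C was also measured in the presence of TG003. The ATF4 targets rose at 35 °C, 23 of 25 with 1 lower, and the same adjusted over the list alone (median 0.69, adjusted p = 1.55e-13, and adjusted p = 0.0913 with an estimated correlation). CHAC1 rose 8.79-fold, SESN2, a stress-induced regulator of mTORC1, 5.77-fold, ATF3 3.23-fold and STC2 2.27-fold. Of 32 heat shock genes, 25 fell and 2 rose (median -0.32, adjusted p = 1.43e-10, and adjusted p = 0.148 with an estimated correlation), or 27 and 2 adjusted over the list alone. HSPA1B was 3.86-fold lower (196 ± 15.1 against 724 ± 63.7 TPM), DNAJB1 3.78-fold, HSPA8 2.6-fold and DNAJA1 2.12-fold lower. The adjusted p over 20 alternatives ran from 7.62e-16 to 0.0913 for ATF4 targets and from 7.46e-11 to 0.148 for heat shock genes. Of 20208 genes 5147 rose and 5243 fell, 51.4% in all, and 580 and 656 of them changed at least 2-fold. The share higher was 49.5%, against 59.8% with limma (5419 and 3638) and 59.3% with library totals alone (6226 and 4267). The 2-fold counts, higher and lower, were 294 and 370 with limma, 696 and 592 with library totals alone, and 1111 and 1393 without a filter.

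Of 76 ribosomal protein genes, 69 fell and none rose at 35 °C in TG003, or 71 adjusted over the list alone (median -0.25, adjusted p = 2.68e-14, and adjusted p = 0.513 with an estimated correlation). Quantile normalization put the median at -0.03 (adjusted p = 0.163, range 7.4e-17 to 0.513). RPL17 was 1.81-fold lower, RPL28 1.52-fold, RPL27A 1.42-fold and RPS24 1.39-fold, the last pair not with quantile normalization (adjusted p = 0.482 and 0.0722, lowest 6.61e-37 and 3.66e-24). Of 14 histone genes, 10 fell and 1 rose, and the same adjusted over the list alone (median -0.58, adjusted p = 0.000146, and adjusted p = 0.148 with an estimated correlation), with HIST2H2BE 2.72-fold, HIST1H3H 2.6-fold, HIST1H2BD 2.41-fold and HIST1H2AC 1.85-fold lower. Of 15 CLK and related kinases, 12 fell and none rose, and the same adjusted over the list alone (median -0.37, adjusted p = 0.000146, and adjusted p = 0.148 with an estimated correlation). DYRK3 was at -0.73 ± 0.07, DYRK4 at -0.71 ± 0.07, DYRK1A at -0.58 ± 0.05 and CLK2 at -0.39 ± 0.04. Of 21 cholesterol genes, 14 fell and 2 rose, or 15 and 2 adjusted over the list alone (median -0.33, adjusted p = 0.000146, and adjusted p = 0.148 with an estimated correlation). MSMO1 was at -1.40 ± 0.11, SQLE at -1.32 ± 0.07, HMGCS1 at -0.90 ± 0.08 (SE) and FDFT1 at -0.65 ± 0.05. Over 20 alternatives the adjusted p ran from 7.31e-05 to 0.148 for histones, 9.48e-05 to 0.148 for the kinases and 7.29e-05 to 0.148 for cholesterol genes.

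Of 26 genes of G2 phase and mitosis, 17 fell and 3 rose at 35 °C in TG003, and the same adjusted over the list alone (median -0.20, adjusted p = 0.0222, and adjusted p = 0.709 with an estimated correlation). CENPE was at -0.65, CENPF at -0.49 and CCNB1, the mitotic cyclin, at -0.47, while CCNA2 rose 1.52-fold (list range 0.00322 to 0.709). Of 23 genes of G1/S and replication, 11 rose and 6 fell, and the same adjusted over the list alone (median 0.09, adjusted p = 0.0245, and adjusted p = 0.513 with an estimated correlation). CDC6, which loads the replicative helicase, rose 2.26-fold, CHAF1B 1.85-fold, PCNA 1.82-fold and E2F1 1.81-fold. The call was lost with the length offset (0.0565), limma (0.0879) and the replicate number as a block. It was also lost without TG003_35 replicate 1 (0.0522), DMSO_39 replicate 1 (0.0563) or 2 (0.053), or TG003_39 replicate 2 (0.0507) or 3 (0.0826), over a range of 0.0148 to 0.513. Of 24 hnRNP genes, 14 fell and 4 rose, or 15 and 4 adjusted over the list alone (median -0.19, adjusted p = 0.0245, and adjusted p = 0.709 with an estimated correlation). HNRNPH2 (-0.50 ± 0.04) and HNRNPF (1.35-fold lower) fell, and HNRNPAB (1.4-fold) and HNRNPUL1 (1.32-fold) rose. Quantile normalization ended that call (adjusted p = 0.163, range 0.000917 to 0.709).

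Other large changes at 35 °C in TG003 were the rises of SAPCD1 (7.48-fold), SLC25A32 (5.58-fold), SH2D3C (5.14-fold) and PHBP9 (4.95-fold). OPRD1 (14.2-fold), SUMO4 (11.3-fold), CMYA5 (9.47-fold) and EFCAB12 (6.72-fold) were lower. Among small RNAs, MIR221 had 6 counts in TG003_35 and 0 in TG003_39, 1.9-fold higher against the floor of 3 counts. It lost its call (adjusted p = 0.0436) without DMSO_35 replicate 1 or 2, TG003_35 replicate 2 or 3, DMSO_39 replicate 1 or 2, or any 1 library of TG003_39 (0.0519 to 0.117, and 0.0062 to 0.117 over 26 alternatives). RF00322 had 13 and 1 counts, a 12.3-fold ratio (95% interval 1.85 to 524). It lost its call (0.0177) without TG003_35 replicate 2, TG003_39 replicate 1 or TG003_39 replicate 3 (0.0596 to 0.0652, lowest over the alternatives 0.00533), and was at 5.12 against 3.17 without TG003_39 replicate 2. SCARNA4 had 0 and 10 counts, 3.51-fold lower with the 0 set to that floor. It lost its call (0.0338) without any 1 library of TG003_35 or without TG003_39 replicate 3 (0.0708 to 0.231, lowest 0.00967). RNA5SP383 had 0 and 6 counts, 2.11-fold lower with the 0 set to that floor. It lost its call (0.0237) without any 1 library of TG003_35 or without TG003_39 replicate 2 (0.0548 to 0.0767, lowest 0.000926). SNORA46 had 3 and 16 counts, a 5.62-fold ratio (95% interval 1.61 to 30.1), and lost its call (0.0186) without TG003_35 replicate 2 or TG003_39 replicate 3 (0.0723 and 0.0769, and 0.0024 to 0.231 over the alternatives). SNORA23, with 8 and 40 counts, was at -2.41 ± 0.54 (adjusted p = 0.00102), and at -3.68 without TG003_35 replicate 1.

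HSPA1A (-1.50 ± 0.16) and HSPH1 (-1.23 ± 0.05) fell at 35 °C in TG003. RBM3 was at -0.08 (adjusted p = 0.183), but at 0.12 with limma (0.0408, range 0.039 to 0.774), and neither CLK4 (-0.14, adjusted p = 0.176) nor SRSF5 (-0.06, adjusted p = 0.254) passed. The mean length of the transcripts assigned to RBM3 was at -0.137 ± 0.014 (log2) in this comparison, which lowers its counts relative to its TPM. CIRBP rose 1.11-fold (adjusted p = 0.00931), a call lost with quantile normalization (0.0612), the length offset (0.165) and without TG003_35 replicate 2 (0.0535), over a range of 0.000828 to 0.165. CLK1 fell by 0.25 (adjusted p = 0.00407), a call lost with limma (0.0866) and quantile normalization (0.0554), lowest 0.000199. CLK3 fell by 0.27, a call lost with limma (0.531), quantile normalization (0.435) and the length offset (0.135), lowest 1.86e-07.

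The interaction tests whether the temperature effect differs between DMSO and TG003. A positive value means a more positive temperature effect in DMSO. The temperature effect on both cold-inducible genes was more positive in DMSO, by 0.57 ± 0.06 for CIRBP (adjusted p = 2.32e-06) and by a 1.72-fold ratio for RBM3 (adjusted p = 2.12e-07). The assigned transcript length of RBM3 had an interaction of 0.098 ± 0.02 (log2), which is part of its ratio. For CLK1 the temperature effect was more negative in DMSO, by -0.89 ± 0.09 (adjusted p = 1.57e-06). In all, 2639 genes had a positive and 3412 a negative interaction, 29.9% of those tested. The positive share was 43.6%, against 31.1% with limma (1421 and 3145), 37% with library totals alone (2239 and 3806) and 49.9% with quantile normalization (2159 and 2171).

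Of 25 ATF4 targets, 18 had a negative interaction and none a positive one, or 20 adjusted over the list alone (median -0.46, adjusted p = 2.89e-11, and adjusted p = 0.157 with an estimated correlation). CHAC1 was at -2.83 ± 0.14, SESN2 at -1.64 ± 0.09, ATF3 at -1.10 ± 0.08 and STC2 at -0.79 ± 0.06 (list range 5.72e-14 to 0.157). Of 76 ribosomal protein genes, 47 were positive and none negative, or 55 adjusted over the list alone (median 0.21, adjusted p = 8.9e-14, and adjusted p = 0.515 with an estimated correlation), and quantile normalization put the median at 0.03 (adjusted p = 0.38, range 3.87e-17 to 0.515). RPS3A was at 0.63 ± 0.07. RPL27A (1.37-fold), RPL14 (1.35-fold) and RPL28 (1.29-fold) lost their calls with quantile normalization (adjusted p = 0.513, 0.249 and 0.195), and RPL27A also with limma (0.335) and the length offset (0.101), against lowest values of 4.3e-15, 1.45e-13 and 1.49e-11. Of 18 transcripts sensitive to decay or to stress, 9 were positive and 1 negative, and the same adjusted over the list alone (median 0.23, adjusted p = 0.00156, and adjusted p = 0.515 with an estimated correlation). GADD45B was at 0.68, SNHG3 at 0.51, SNHG1 at 0.50 and SNHG15 at 0.44, and quantile normalization ended the call (0.146, range 0.000414 to 0.515). Of 14 histone genes, 6 were positive and none negative, and the same adjusted over the list alone (median 0.41, adjusted p = 0.015, and adjusted p = 0.515 with an estimated correlation). HIST2H2BE was at 1.20 ± 0.15, HIST1H3H at 1.07 ± 0.12, HIST1H2BD at 0.65 ± 0.14 and HIST1H2AC at 0.50 ± 0.12, and the list lost its call without DMSO_39 replicate 1 (median 0.42, adjusted p = 0.0513, range 0.00599 to 0.515).

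Of 32 heat shock genes, 12 had a positive and 4 a negative interaction, or 13 and 4 adjusted over the list alone (median 0.13, adjusted p = 0.0027, and adjusted p = 0.515 with an estimated correlation). BAG3 was at 0.74 ± 0.09 (SE), DNAJB1 at 0.58 ± 0.07, HSPA4 at 0.38 ± 0.05 and CHORDC1 at -0.81 ± 0.11. Of 24 hnRNP genes, 12 were positive and 3 negative, or 12 and 4 adjusted over the list alone (median 0.17, adjusted p = 0.00493, and adjusted p = 0.596 with an estimated correlation), with PTBP2 at 0.76 ± 0.11, HNRNPH2 at 0.63 ± 0.06, HNRNPR at 0.58 ± 0.08 and HNRNPA0 at 0.33 ± 0.05. Quantile normalization ended both calls (adjusted p = 0.303 each, ranges 0.000629 to 0.515 and 0.000102 to 0.596). Of 20 ER genes, 8 were positive and 1 negative, and the same adjusted over the list alone (median 0.16, adjusted p = 0.00919, and adjusted p = 0.515 with an estimated correlation). EDEM1 was 1.34-fold, HSPA5 1.28-fold and PDIA4 1.26-fold on the positive side, and SEL1L at -1.07 ± 0.08. The ER call was lost with limma (0.0506) and quantile normalization (0.299), over a range of 0.00131 to 0.515. Of 13 mitochondrially encoded genes, 7 were positive and none negative, or 8 adjusted over the list alone (median 0.17, adjusted p = 0.00678, and adjusted p = 0.614 with an estimated correlation), while quantile normalization, with the same limit on top ranks, put the median at 0.00 (adjusted p = 0.851), turned MT-CO2 to -0.07 and put MT-CO3 at 0.00. The list was also lost with limma (0.108), over a range of 0.000774 to 0.851. MT-CO3 was at 0.24 ± 0.06, MT-CO2 at 0.21 ± 0.05, MT-ND1 at 0.21 ± 0.05 and MT-ND4 at 0.21 ± 0.06, none of them past the threshold with limma (adjusted p = 0.101, 0.129, 0.144 and 0.156, lowest 0.000114, 0.000115, 0.000622 and 0.000415).

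The largest positive interactions among well-measured genes were those of OPRD1 (17.8-fold, adjusted p = 4.35e-11), CMYA5 (8.45-fold), SUMO4 (7.95-fold), SOWAHD (4.94-fold), BAALC-AS1 (4.27-fold), EFCAB12 (3.9-fold) and HIST1H2BL (3.53-fold). HIST1H2BL was at 1.12 against 1.82 and lost its call without DMSO_35 replicate 1 (adjusted p = 0.186, range 0.00306 to 0.186). Among well-measured genes the largest negative interactions after CHAC1 were those of SAPCD1 (-2.34 ± 0.20), CTH (-2.08 ± 0.07), ESCO1, a cohesin acetyltransferase (-1.87 ± 0.10, and -1.23 with the length offset), ANKRD10-IT1 (-1.85) and SLC25A32 (-1.82). RNA5SP383 was called with 3, 1, 0 and 6 counts in DMSO_35, DMSO_39, TG003_35 and TG003_39, too few for a fold. Its call (adjusted p = 0.0369) was lost without any 1 library other than DMSO_39 replicate 1 and TG003_39 replicate 1 (0.0587 to 0.075, and 0.00074 to 0.103 over 25 alternatives). SNORA71C had 3, 19, 16 and 5 counts and lost its call (0.0295) without DMSO_35 replicate 2 or 3, TG003_35 replicate 1, DMSO_39 replicate 3, or TG003_39 replicate 2 or 3 (0.06 to 0.101, and 0.00671 to 0.148 over the alternatives). RF01979 had 6, 28, 28 and 14 counts and lost its call (0.0253) without DMSO_35 replicate 3, TG003_35 replicate 1, DMSO_39 replicate 3 or TG003_39 replicate 3 (0.0572 to 0.0873, lowest 0.0174).

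HSPH1 had an interaction of 0.47 ± 0.08 (adjusted p = 0.000148) and HSPA1A of 0.80 (adjusted p = 0.0157), the latter lost with limma (0.0739) and without DMSO_35 replicate 1 (0.0666), over a range of 0.00326 to 0.0937. SRSF5 was at -0.45 ± 0.06 (adjusted p = 2.81e-05), but at -0.04 with the length offset (0.754), and its call was lost with limma (0.182) and quantile normalization (0.0826), lowest 3.55e-11. CLK2 (0.05, adjusted p = 0.509), CLK3 (0.15, adjusted p = 0.0813) and CLK4 (-0.19, adjusted p = 0.252) did not pass. CLK3 passed with protein-coding genes alone (0.0402).

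In the median, genes called for temperature in DMSO changed less in TG003. Over 9 ways of calling them in 2 against 2 DMSO libraries, their median signed change was 0.362 in the left-out DMSO pair and 0.269 in TG003. The share kept was 74.9% ± 6.6 (SD over the 9 ways, range 0.674 to 0.885 as a ratio). Genes higher at 35 °C were at 0.359 and 0.302, and genes lower at 35 °C at -0.366 and -0.244. With quantile normalization these values were 0.368 and 0.276, and -0.366 and -0.268. With a pseudocount of 0.1 TPM they were 0.392 and 0.372, and -0.402 and -0.218. The difference between the directions thus depends on the processing. The median hides a mixture. Among all 9027 genes called for temperature in DMSO, 3617 also had a called interaction. In TG003 1779 of these had the opposite sign, 1057 a smaller effect of the same sign and 781 a larger one. Calling and measuring used the same DMSO libraries here, which favours a smaller effect in TG003. Of 5960 genes called for temperature in both treatments, 86.4% changed in the same direction. Of 7635 called for TG003 at both temperatures, 93.7% did, with 3473 higher in both against 1446 expected from independent calls.

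Across genes, which are not independent replicates, the mean temperature effect and the mean TG003 effect correlated at r = -0.335 (rho = -0.315), against -0.077 ± 0.028 in 20 simulations of unchanged groups. The TG003 effects at 35 °C and 39 °C, which share no library, correlated at r = 0.669 (rho = 0.677), against 0.003 in the simulations, and at 0.329 without a filter on expression. The temperature effects in DMSO and TG003 correlated at r = 0.389 (rho = 0.471), against 0.004 in the simulations. That value was 0.17 without a filter and 0.246 with a pseudocount of 0.1 TPM. Comparisons that share the same DMSO libraries carry a built-in correlation. Temperature in DMSO against TG003 at 35 °C gave r = -0.34 where the simulations gave -0.543, but its covariance of -0.132 was more negative than the simulated -0.0549. Against TG003 at 39 °C r was 0.093 where the simulations gave 0.449, and the covariance of 0.0467 lay near the simulated 0.044. This r was 0.263 without a filter and 0.197, 0.174 and 0.164 with pseudocounts of 0.1, 1 and 5 TPM. It was 0.161 with quantile normalization, 0.059 with library weights and -0.01 for protein-coding genes. It was 0.055 without DMSO_35 replicate 3, 0.154 without DMSO_39 replicate 2 and 0.161 without DMSO_39 replicate 3. The covariance of this pair was 0.414 without a filter and -0.00269 for protein-coding genes. Without DMSO_35 replicate 3 it was 0.0295, and without DMSO_39 replicate 3 it was 0.0865. These are 5 pairs in all.

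**Figure D3:**
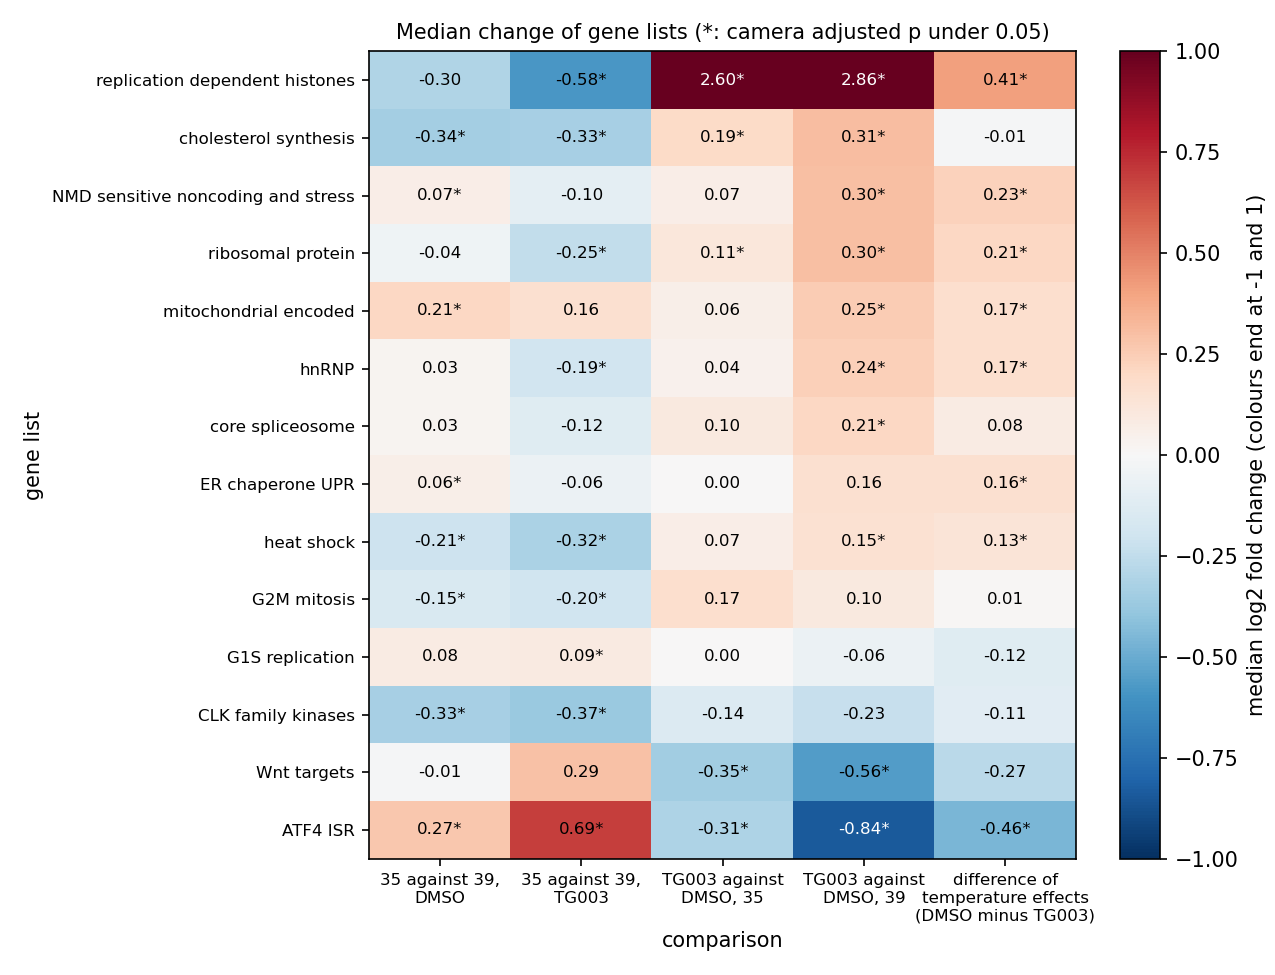
Median log2 change of the members of 14 gene lists (vertical axis, those called at least once) in 5 comparisons (horizontal axis), as colour from -1 to 1, with a star where the camera test passed. Histones had a median of 2.60 and 2.86 with TG003, while quantile normalization turned the ribosomal protein median at 35 °C from 0.11 to -0.02 and put the mitochondrial median at 0.00 in the 3 comparisons where that list was called.

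Of 29 gene lists, 15 were called in none of the 5 comparisons with camera. That test sets a list against other genes, so a list not called can hold changed members. For temperature in DMSO, 2 of 4 cold-inducible genes rose and 1 fell (changes of -0.51 to 0.72). Of 14 SR proteins 2 rose and 6 fell, of 20 clock genes 5 and 10, and of 28 immediate early genes 10 and 10. The 4 cold-inducible RNA-binding protein genes had medians of -0.17 to 0.34 (adjusted p = 0.272 to 0.912), the 14 SR proteins -0.09 to 0.11 (0.441 to 1) and the 14 decay factors -0.10 to 0.16 (0.214 to 0.941). Medians were -0.28 to 0.03 for 20 genes of the circadian clock (0.214 to 0.941), -0.03 to 0.04 for 28 immediate early genes (0.768 to 0.951) and -0.08 to 0.15 for 18 p53 targets (0.513 to 0.941). They were -0.12 to 0.16 for 22 genes of homologous recombination (0.107 to 1), -0.11 to 0.14 for 18 hypoxia genes (0.11 to 0.941) and -0.27 to 0.23 for 13 NRF2 targets (0.202 to 0.959). The 5 AhR targets had medians of -0.18 to 0.07 (0.214 to 0.962), the 10 interferon response genes -0.13 to 0.09 (0.441 to 0.941) and the 3 metallothioneins -0.19 to 0.29 (0.768 to 1). Markers of other cell types had medians of -0.28 to 0.20 for 3 fibroblast genes (0.331 to 0.959), -0.20 to 0.29 for 5 epithelial genes (0.234 to 0.998) and -0.09 to 0.61 for 6 leukocyte genes (0.0628 to 0.761). The median, mean and test had the same sign in every called list. Among lists not called they differed in 2 for temperature in DMSO, 4 for TG003 at 35 °C, 2 for TG003 at 39 °C, 7 for temperature in TG003 and 7 for the interaction.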

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

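The tests in this part were chosen after the results were seen for carry-over of RNA without a tail, more cells in S phase, longer transcripts and DNA spread evenly, and the others were fixed beforehand.

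The temperature effect differed between DMSO and TG003 in 6051 genes. Among gene lists, the median interaction was -0.46 for ATF4 targets, 0.41 for histones, 0.23 for transcripts sensitive to decay or to stress and 0.21 for ribosomal proteins. It was 0.17 for hnRNPs, 0.17 for mitochondrially encoded genes, 0.16 for ER chaperones and 0.13 for heat shock genes. None of these 8 lists was called with an estimated correlation (adjusted p = 0.157 with an estimated correlation for ATF4 targets and 0.515 to 0.614 for the others). Single genes with a positive interaction were OPRD1 (4.15), CMYA5 (3.08), SUMO4 (2.99), SOWAHD (2.30), BAALC-AS1 (2.09), EFCAB12 (1.96) and HIST1H2BL (1.82), the last at 1.12 and not called without DMSO_35 replicate 1 (adjusted p = 0.186, range 0.00306 to 0.186). RNA5SP383 had a fitted 5.79, which is no bound at 0 to 6 counts per group. Negative interactions were those of CHAC1 (-2.83), SAPCD1 (-2.34), CTH (-2.08), ESCO1 (-1.87), ANKRD10-IT1 (-1.85) and SLC25A32 (-1.82). SNORA71C (-3.63, with 3 to 19 counts per group) and RF01979 (-2.62, with 6 to 28) rest on few counts and lost their calls without any 1 of 6 and of 4 libraries. Of the genes followed throughout, HSPA1A was at 0.80 (not called without DMSO_35 replicate 1, adjusted p = 0.0666, range 0.00326 to 0.0937), RBM3 at 0.78, CIRBP at 0.57, HSPH1 at 0.47, SRSF5 at -0.45 and CLK1 at -0.89.

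Relabelling the samples shows how many calls other groupings of the same libraries give. For each of the 4 pair comparisons the real split had the most calls (9027, 9588, 12513 and 10390), the highest other split had 0, and 1 of 10 splits reached the real count. With 10 splits a share under 0.05 is out of reach. Every other split also mixes both groups, which puts their difference into the spread within groups and lowers the number of calls. For the interaction 2 of 100 regroupings reached the real count of 6051 genes. The other 1 of these had 6366 calls and put 5 of the 39 °C libraries on one side, so it carries the temperature groups themselves. Regrouping all 12 libraries mixes temperatures and treatments, so the effects of both enter the spread within groups. The median of the other regroupings was 0 calls. They stand for no effect of any kind, so the 2 of 100 cannot test the interaction by itself.

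Histone RNAs rose with TG003 (adjusted p = 0.0437 with an estimated correlation at 39 °C), although their messages normally carry no poly(A) tail and the libraries were made from polyadenylated RNA. Carry-over of tail-less RNA would raise other such RNAs about as much. The 6 of 27 with enough counts had a median of 0.35 (SD 0.65) at 39 °C, against 2.86 for the histones. Carry-over may thus account for a part, but these 6 had mean counts of only 10.2 to 37 per library. So few reads cannot show whether carry-over of histone messages reaches the size of the rise. The 6 RNAs ran from -0.09 to 1.67 and the 14 histones from 1.25 to 4.08, so the highest, SCARNA10 (adjusted p = 0.00359, named after its value was seen), lay within the histone range. Reads moved between near-identical copies would leave the sum of 87 histone cluster genes unchanged, which rose by 2.92. More cells entering S phase would raise G1/S genes, whose median was -0.06 with 7 higher and 10 lower of 23. Cell cycle phase was not measured, so this list cannot show whether cells stayed longer in S phase. A biological difference that the design names stays among the open explanations, as untested.

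Long noncoding genes and pseudogenes were called higher with TG003 more often than protein-coding genes. Thinning all libraries to one size left a gap of 34 points at 39 °C, 75% against 41%, so library size may not be the cause. Genomic DNA is possible, since the summed count of 381 olfactory receptor genes not expected in this line rose by 1.46 ± 0.16 at 39 °C. Yet 256 of them had no count where evenly spread DNA would leave 1.4e-08, and 10 genes held 84.5% of the TG003 counts. Noncoding genes inside or within 10 kb downstream of a protein-coding gene on the same strand had a median 0.16 above that of the others, so reads from introns or past gene ends could add to the pattern. The 4082 others still had a median of 0.23 at 39 °C, against -0.08 for protein-coding genes. The strandedness of the libraries is not given, so this split may not separate all such reads. A biological difference that the design names stays among the open explanations, as untested.

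Ribosomal protein genes rose with TG003 at 39 °C, 73 of 76 with a median of 0.30 (adjusted p = 0.484 with an estimated correlation). Short abundant genes matched on length, GC content and level had a median of 0.23, which may account for most of the rise. Of 1000 draws, 0 reached the median of the ribosomal genes, but the highest was also 0.30 when rounded. Scaling could also produce it, as quantile normalization gave 0.02, but size factors gave 0.31 and scaling without mitochondrially encoded genes 0.30, and quantile normalization leaves abundant genes (median rank 80 here) less room to change. Longer assigned transcripts may not explain it, since the length offset left 0.25. A biological difference that the design names stays among the open explanations, as untested.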

How the results depend on the processing

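Library totals alone, DESeq2, the length offset, the single-library runs of the list tests, the correlations without a filter, for protein-coding genes and with library weights, and all alternatives of the last 3 correlations were chosen after the results were seen, and the cause was not tested. Of 7626 results of named genes under alternatives, 7168 kept a call and its direction, 227 lost the call and 11 turned. For genes not called, 195 stayed so with the same sign, 16 stayed so with the other sign, 6 gained a call and 3 gained it with the other sign. RPL14 with TG003 at 35 °C turned to -0.031 with limma and with pseudocounts of 0.1 and 5 TPM, and to -0.082 with quantile normalization. RPL28 turned to -0.039, -0.039, -0.038 and -0.087 in the same order. MT-CO2 turned to -0.066 with quantile normalization, with TG003 at 39 °C and in the interaction, where MT-CO3 and the mitochondrial list were at 0. RBM3 in TG003 turned to 0.124, 0.125 and 0.119 with limma and pseudocounts of 0.1 and 5 TPM. Lists called for temperature in DMSO, TG003 at 35 °C, TG003 at 39 °C, temperature in TG003 and the interaction numbered 8, 5, 10, 9 and 8. With an estimated correlation they numbered 0, 1, 3, 0 and 0, while fry, which tests a list against no change and not against other genes, called 20, 22, 25, 20 and 14. With quantile normalization they numbered 5 for temperature in DMSO, 5 for TG003 at 39 °C and 2 for the interaction, and with limma 6 for TG003 at 39 °C. The replicate number as a block gave 8918, 9505, 12492, 10332 and 5926 genes. It ended 4 of 40 list calls, of ER chaperones, transcripts sensitive to decay or to stress, hnRNPs and G1/S genes. The share kept was 0.671 with a pseudocount of 5 TPM. The correlation of the temperature and TG003 effects was -0.27 with limma, -0.251 and -0.281 with pseudocounts of 0.1 and 5 TPM, -0.275 with quantile normalization, -0.24 without a filter, -0.413 for protein-coding genes, and between -0.369 (without DMSO_35 replicate 3) and -0.297 (without DMSO_39 replicate 3). That of the TG003 effects at 35 °C and 39 °C was 0.544, 0.506, 0.553 and 0.518 in the same order, 0.329 without a filter, 0.795 for protein-coding genes, 0.608 from a mean TPM of 5, 0.736 with library weights, 0.71 with DESeq2, 0.659 with the length offset, and between 0.643 (without DMSO_35 replicate 2) and 0.672 (without DMSO_39 replicate 1). That of the temperature effects in DMSO and TG003 was 0.289, 0.246, 0.307, 0.284, 0.17, 0.542, 0.35, 0.458, 0.426 and 0.381 in this order, and between 0.363 and 0.39 with a library left out. Temperature in DMSO against TG003 at 35 °C gave -0.46 without a filter, -0.285 for protein-coding genes, and -0.421 to -0.308 with a library left out. Against TG003 at 39 °C it gave 0.174, 0.197, 0.164, 0.161, 0.263, -0.01, 0.127 and 0.059 from limma to library weights in this order, and 0.055 to 0.161 with a library left out.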

Other observations

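The length tests in this part were chosen after the results were seen. The mean length of the transcripts assigned to a gene, taken from counts over TPM, changed by at least 1.15-fold in many of 11005 genes with a mean TPM of at least 10. With TG003 at 39 °C it rose in 394 genes and fell in 1271, and with TG003 at 35 °C it rose in 305 and fell in 659. For temperature in DMSO the numbers were 172 longer and 349 shorter, for temperature in TG003 441 and 297, and for the interaction 108 and 302. RPAP2, a phosphatase of RNA polymerase II, and SRP19, part of the signal recognition particle, became longer with TG003 at 39 °C (adjusted p = 3.11e-07 and 1.06e-07). USP7, a deubiquitinase, was at -1.05 ± 0.04 and TIA1, a regulator of splicing, at -0.98 ± 0.04 (adjusted p = 2.41e-07 and 3.2e-07). In DMSO at 35 °C SRSF5 was shorter by -0.39 ± 0.04 (adjusted p = 0.000634) and ZNF585A by -1.09 ± 0.08 (adjusted p = 8.24e-05). A change of isoform would give such values, and which isoform changed was not measured.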
